A study of Stylophora pistillata with 24 samples.

How the data were processed

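Messenger RNA was sequenced from whole-organism tissue of the stony coral Stylophora pistillata, a branching reef builder that broods its larvae (planulae). The 24 libraries formed 8 groups of 3. Adults and planulae came from the natural reef at 5 m (shallow) or 45 m (deep, the mesophotic reef). Juveniles settled from shallow planulae were grown in settlement chambers on the reef and collected at 8 or 60 days. They were grown either at 5 m (controls) or at 45 m (translocated). The design text describes a full exchange between depths; juveniles of deep origin were not analysed here. Per the labels' protocols, libraries were made from poly(A) RNA (input 500 ng of total RNA, integrity number above 7.7), with molecular identifiers added ahead of PCR. The read length is stated in 2 ways in the labels and was not used. Nothing in the labels says whether the 3 samples of a group were separate colonies or broods, so the p-values measure the spread between these samples, which may be technical in part.

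The authors deposited a table of raw counts per gene. Per the submitters' processing notes, reads were handled with FastQC, MultiQC, cutadapt, Trimmomatic and DESeq2. The aligner, the counter, the genome build, the use of strand and the treatment of molecular identifiers are not given in the sources used here. Reads of overlapping genes, antisense partners and near-identical gene copies may therefore be shared, and counting intervals and floors cover counting error only. The table held 33281 genes, of which 1031 had no count in any library, and every column belonged to a labelled library. Totals ran from 13.57 M to 35.78 M counts per library (median 24.32 M, where M is 1e6). Gene names were taken from a second table deposited by the authors, which covers 26602 genes, and 15322 genes (46.0%) had an informative product name. The 6679 genes outside that table held 0.54% of all counts. Of 24389 NCBI gene numbers in it, 21217 were also in the reference gene table. Names are automatic homology names ("-like") and are printed with the authors' gene identifiers.

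The same annotated table holds the authors' log2 fold changes and adjusted p-values from DESeq2 for adults and planulae, per the file headers. Their column for deep against shallow planulae repeats the values of their column for deep planulae against deep adults in all 26602 genes, so only their adult comparison was set beside the present one. Of 24724 genes with an adjusted p in the authors' deposited table that were also tested here, 2735 were called there, 1966 here and 1827 in both, all 1827 with the same sign.

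Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered with filterByExpr on the 8 groups (25735 kept) and scaled by the trimmed mean of M-values (TMM). All 24 libraries entered 1 quasi-likelihood fit with group means and 16 residual degrees of freedom. Each comparison was a contrast in that fit, tested 2-sided with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Unless another method is named, every adjusted p of a gene comes from this test. Log2 fold changes are given with their standard error (SE), and levels as counts per 1e6 counts (CPM), mean ± SD of 3 libraries. The 10 comparisons were deep against shallow planulae, deep against shallow adults, translocated against control juveniles at each age, 4 steps of age along the shallow and the translocated line, and the 2 differences between depth effects.

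The comparisons, their tests and alternatives, the gene lists and the rule for named genes were set before the data were examined. The tests of explanations in the closing section were chosen after the results were seen, apart from 2 whose predictions were written first. In each comparison of 2 groups the rule named the 6 largest rises and 6 largest falls among called genes with an informative name, a mean of at least 10 CPM in the higher group and no overlap between the groups' libraries, which chance gives for 10% of genes with 3 against 3. It also named the member of each gene list with the smallest p, and up to 3 members of a list past its threshold. Where a group had 0 counts, a fold is given as "at least" against a floor of 3 counts per library. Where a group had 1 to 3 counts in all, the ratio is given with its 95% counting interval.

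The 27 gene lists were picked by words in the product names. They were fluorescent proteins, opsins and phototransduction, circadian clock and blue-light receptors, skeletal organic matrix, carbonic anhydrases and calcification ion transport, nematocyst structure, venom and toxins, dinoflagellate photosynthesis, symbiosis nutrient exchange, heat shock proteins and chaperones, antioxidant defence, innate immunity, apoptosis, cilia, germ line with meiosis and eggs, cell cycle and DNA replication, cytosolic ribosome, oxidative phosphorylation, glycolysis and gluconeogenesis, fatty acid oxidation, lipid synthesis and storage, extracellular matrix and adhesion, neurons and synapses, developmental transcription factors and signalling, DNA repair, proteasome, and digestive and gland enzymes. The nematocyst list held 1 gene and was not tested as a list. The dinoflagellate list caught coral gene models named after plant proteins, so it says nothing about algal RNA. The ribosome list also caught 4 ribosomal protein S6 kinases. Lists were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the 26 lists tested), which compares a list with all other genes. Camera was repeated with a correlation estimated from the residuals, and fry, which asks whether a list moves on balance 1 way, was run as another alternative. Setting genes with 0 counts in a group to their bound moved no list median by more than 0.44 (log2).

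Genes called in the native comparisons were followed into the other depth comparisons by the share with the same sign and by fry with signed weights. Alternatives were DESeq2 1.42.0, median-ratio size factors, no filter or a stricter filter, only the libraries of the groups compared, the 50 most abundant genes left out, a replicate block, and each library left out in turn. The pipeline was tested on simulated counts with 50 genes changed by each of 4 amounts. For deep against shallow planulae it recovered 0%, 14%, 72% and 92% of genes changed by 0.58, 1, 2 and 4 on the log2 scale, with 1.1% false calls, and for the 60-day translocation 0%, 10%, 74% and 90% with 2.2% false calls. For the difference between the translocation effects at both ages it recovered 0%, 0%, 40% and 70% with 1.8% false calls. In the simulated comparison of planulae, 23.1% of the DESeq2 calls were false (30 calls among 24698 unchanged genes). DESeq2 recovered 4%, 20%, 78% and 98% of the changed genes there. Few genes were changed in the simulation, and its counts were drawn with the dispersions of the edgeR fit. That share therefore cannot be carried over to the higher counts of called genes that DESeq2 gave in the real data.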

Results

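The series asked how a reef coral lives over a depth gradient from the planula through 8-day and 60-day juveniles to the adult, and what happens to shallow juveniles moved to the mesophotic reef. Life stage set the largest share of variation between the 24 libraries. On the first principal component (33.8% of variance) planulae lay at 171 to 227, juveniles at −53.2 to −11.2 and adults at −132 to −81.5. Within planulae and adults the libraries of 1 depth resembled each other more than those of the other depth (median Spearman 0.956 and 0.954 within deep and shallow planulae, 0.906 between them). One shallow planula library (replicate 1) lay at 178, beside the deep planulae at 171 to 179, while the other 2 lay at 223 and 227. Deep adult replicate 3 stood apart from its group and had the smallest total (13.57 M counts). Group totals averaged 16.17 ± 2.37 M in deep adults and 16.91 ± 1.38 M in translocated 60-day juveniles against 26.02 ± 1.73 and 23.65 ± 5.13 M in their shallow counterparts (mean ± SD, n = 3 libraries per group).

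**Figure D1:**
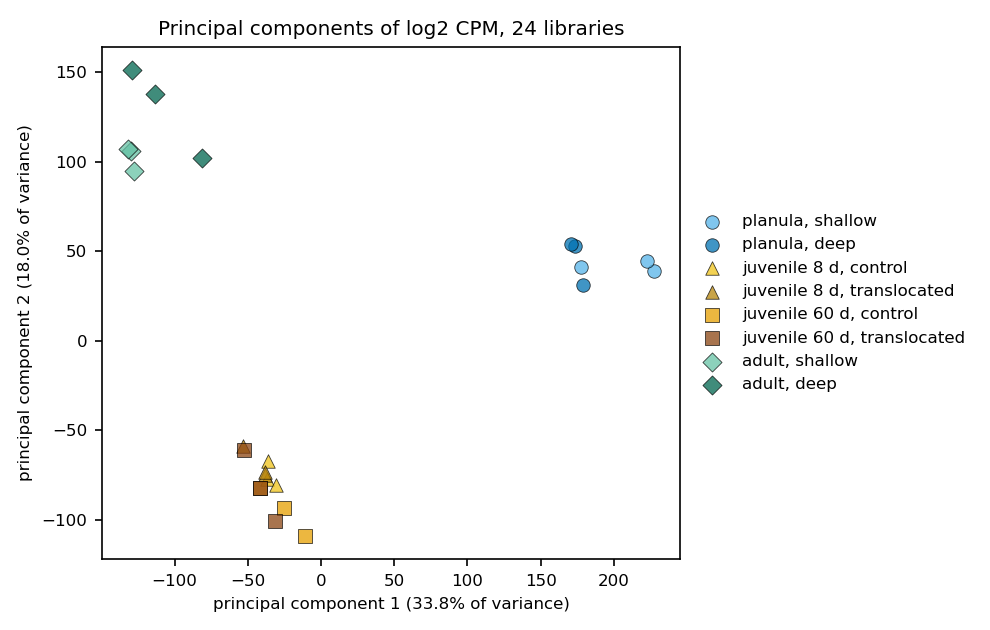
Principal components 1 (33.8% of variance) and 2 of log2 CPM, 1 point per library, coloured by group. Planulae lie apart at 171 to 227 on component 1, and shallow planula replicate 1 at 178 sits with the deep planulae.

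The number of genes that differed with depth ran from 5901 in planulae to 1 in 8-day juveniles. At an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 5901 of 25735 genes differed between deep and shallow planulae (22.9%; 3209 higher and 2692 lower at depth, or 2089 and 2676 with only the planula libraries fitted) and 2063 between deep and shallow adults (958 higher, 1105 lower, or 433 genes with only the adult libraries fitted). Translocation changed 1 gene at 8 days and 616 at 60 days. Most of these 616 were not called with only the 60-day libraries fitted. Steps of age changed 10044 genes from shallow planula to 8-day control juvenile and 2202 from 8 to 60 days in controls. They changed 1900 over the same time in translocated juveniles and 8060 from the 60-day control to the shallow adult. The first and last of these steps also go between the natural reef and settlement chambers, so age and rearing cannot be told apart there.

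**Figure D2:**
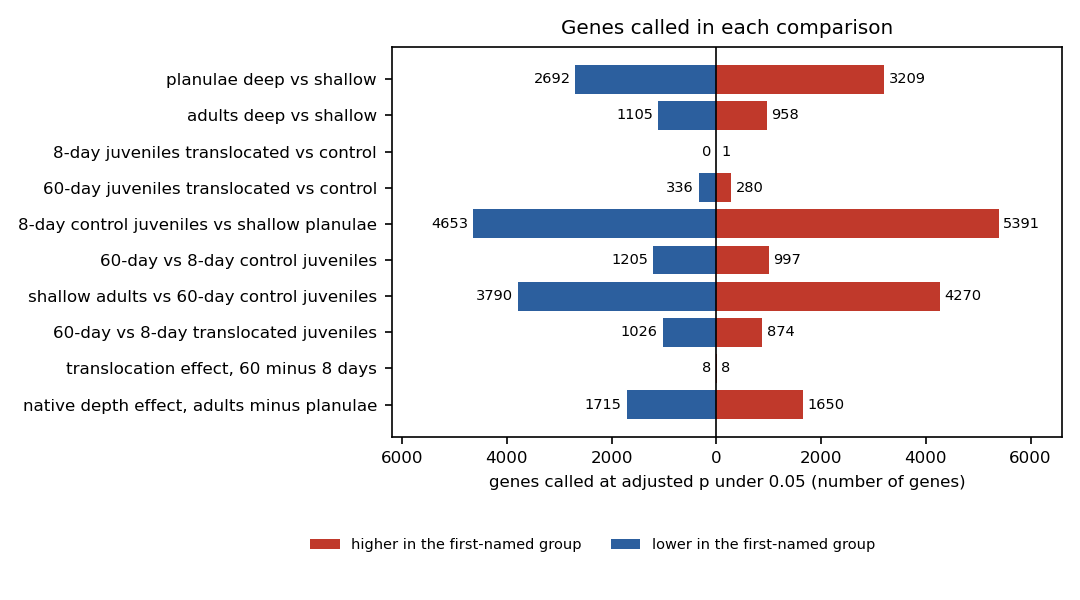
Genes higher and lower at an adjusted p under 0.05 in each comparison (number of genes, 3 libraries per group). In the fit of all libraries, groups from 45 m and 5 m differed in 5901 genes in planulae, 2063 in adults, 1 in 8-day and 616 in 60-day juveniles.

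The first question was how native planulae differ between the depths. Deep planulae carried less RNA for protein synthesis and for making energy. Of 82 cytosolic ribosome genes 65 fell and 1 rose, 16 were not called, and the median log2 fold change was −1.25 (camera adjusted p = 2.05e-26, adjusted p = 0.389 with an estimated correlation). Ribosomal protein L10a (gene23030), a part of the large subunit, fell from 1070 ± 215 to 300 ± 36.7 CPM (log2 fold change −1.83, SE 0.22, adjusted p = 2.35e-05), and L9 (gene22401) from 2470 ± 300 to 796 ± 62 CPM. Of 56 oxidative phosphorylation genes 38 fell, none rose and 18 were not called (median −0.90, camera adjusted p = 2.33e-16, adjusted p = 0.389 with an estimated correlation). The 49 kDa subunit of NADH-ubiquinone oxidoreductase (gene13246), which is part of respiratory complex I, went from 443 ± 57.9 to 169 ± 7.06 CPM (−1.39, SE 0.21, adjusted p = 0.000166). Adjusted over the list alone, 71 ribosome genes fell and 1 rose, and 45 oxidative phosphorylation genes fell.

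Fuel use followed the same direction in deep planulae. Of 55 fatty acid oxidation genes 19 fell and none rose (22 and 4 adjusted over the list alone; median −0.49, camera adjusted p = 0.000124), among them medium-chain acyl-CoA dehydrogenase (gene19811, 2050 ± 411 to 848 ± 73.4 CPM, adjusted p = 0.00112). Glycolysis and gluconeogenesis lost 11 of 22 genes and gained 2 (12 and 2 over the list alone; median −0.54, camera adjusted p = 0.000916), with enolase (gene13500) going from 267 ± 17.4 to 138 ± 10.2 CPM (−0.96, SE 0.17). Antioxidant defence fell in 22 and rose in 7 of 85 genes (27 and 7 over the list alone; median −0.38, camera adjusted p = 0.00102); glutathione peroxidase (gene7287), which removes hydroperoxides, went from 47.3 ± 3.5 to 15.6 ± 1.71 CPM. In the proteasome 8 of 44 genes fell and 2 rose, with the same counts over the list alone (median −0.39, camera adjusted p = 0.00505). None of these lists passed camera with an estimated correlation (adjusted p = 0.389 for fatty acid oxidation, glycolysis and antioxidant defence, 0.903 for the proteasome).

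Deep planulae had more RNA for building and patterning the body. In extracellular matrix and adhesion 82 of 299 genes rose and 16 fell (93 and 19 over the list alone; median 0.68, camera adjusted p = 0.000103, adjusted p = 0.389 with an estimated correlation), led by a metalloproteinase with thrombospondin motifs (ADAMTS; gene21139), at 279 ± 28.1 against 53.4 ± 8.11 CPM. Developmental transcription factors and signalling gained 89 of 356 genes and lost 16 (99 and 20 over the list alone; median 0.60, camera adjusted p = 0.000188, adjusted p = 0.389 with an estimated correlation). Bone morphogenetic protein 7 (gene23591), a signal in body patterning, rose by 1.76 (SE 0.21, adjusted p = 1.77e-05) from 21.1 ± 4.12 to 71.7 ± 14.5 CPM. Symbiosis nutrient exchange rose in 37 and fell in 6 of 112 genes (40 and 8 over the list alone; median 0.63, camera adjusted p = 0.00145, adjusted p = 0.389 with an estimated correlation). The ammonium transporters Rh type A (gene15054, 2.98, SE 0.40, adjusted p = 6.51e-05) and Rh type B (gene15055, 2.95, SE 0.45) both rose.

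Several single genes were nearly confined to planulae of 1 depth. Neuroendocrine convertase 2 (gene12209), a hormone-processing protease, had 31.8 ± 7.76 CPM in shallow and 1 count in all deep planulae (ratio 2140, 95% counting interval 384 to 84500, adjusted p = 2.81e-10). Spondin-1 (gene26965), a matrix protein, had 89.5 ± 22.6 CPM in shallow planulae (ratio 6020, 1080 to 238000) and STELLO1 (gene14515) 15.3 ± 2.32 CPM (ratio 514, 142 to 4240). The other way, a gene named after the fluorescent chromoprotein amFP486 (gene22464) had 31.2 ± 32.9 CPM in deep and 1 count in shallow planulae (ratio 1270, 228 to 50300, adjusted p = 0.000271), and protein kinase 4 (gene25682) was at least 83.3-fold higher in deep planulae. Another gene of the amFP486 name (gene28123) fell from 27.1 ± 11.2 to 1.42 ± 0.862 CPM at depth (−4.25, adjusted p = 0.0369). Skeletal organic matrix protein 5 (gene27240) rose from 12.7 ± 4.67 to 548 ± 25.2 CPM (5.43, SE 0.59, adjusted p = 1.01e-05). Caspase-8 (gene10577), a starter of cell death, rose by 2.28 (SE 0.24) and cryptochrome-1 (gene25041), a blue-light receptor, fell from 95.1 ± 19.9 to 40.8 ± 6.17 CPM. Apoptosis as a list rose in 6 and fell in 11 of 39 genes (camera adjusted p = 0.0697), and carbonic anhydrases, the coral genes named after dinoflagellate photosynthesis proteins and the lipid list did not differ from other genes (adjusted p = 0.85, 0.985 and 0.112). Without shallow planula replicate 2 or 3, the number of genes called went from 5901 to 3757 or 3833.

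The next question was which depth differences adults carry. Deep adults and deep planulae had 502 genes called the same way, some with very large differences, but deep adults had no broad fall in energy genes. Neuroendocrine convertase 2 (gene12209) had 19.1 ± 3.14 CPM in shallow and 1 count in all deep adults (ratio 1060, 190 to 41800, adjusted p = 1.23e-09). Skeletal organic matrix protein 5 (gene27240) was 94.8 ± 47.6 against 0.711 ± 0.417 CPM (7.07, SE 0.65, adjusted p = 1.34e-06), and the inactive pancreatic lipase-related protein 1 (gene13103) fell in deep adults (−2.71, SE 0.26) as in deep planulae (−3.24, SE 0.27). Carbonic anhydrase 2 (gene25728), which turns CO2 into bicarbonate, fell from 1140 ± 361 to 257 ± 33.9 CPM (−2.15, SE 0.41, adjusted p = 0.00282). The heat shock protein HSP70 12A (gene9887) had 64.1 ± 10.2 CPM in deep adults (ratio 3190, 883 to 26300), a protein named after streptococcal M protein (gene26970) was at least 427-fold higher, and the mucosal defence protein DMBT1 (gene21310) fell from 246 ± 42.1 to 0.32 ± 0.321 CPM. The NDUFA4 subunit of cytochrome c oxidase (gene17976) fell from 28.6 ± 6.96 to 7.82 ± 1.78 CPM (−1.87, SE 0.30, adjusted p = 0.000695). Intraflagellar transport protein 22 (gene13142) was at least 32.6-fold lower in deep adults.

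Among lists, the cytosolic ribosome stood higher than other genes in deep adults (1 of 82 rose, none fell, none over the list alone; median 0.55, camera adjusted p = 3.11e-06, adjusted p = 0.86 with an estimated correlation). Its call was lost without deep adult replicate 3 (median 0.10, adjusted p = 0.627). The proteasome had no called gene of 44 (none over the list alone; median 0.37, camera adjusted p = 0.00981, adjusted p = 0.86 with an estimated correlation); without deep adult replicate 3 its median was −0.03 (adjusted p = 0.926) and without shallow adult replicate 1 0.35 (adjusted p = 0.0519). Oxidative phosphorylation fell in 4 of 56 genes and rose in none, with a median of 0.45 (camera adjusted p = 0.287). In lipid synthesis and storage 5 of 22 genes fell and none rose, and in innate immunity 16 fell and 7 rose of 267 (camera adjusted p = 0.287 for each). Without shallow adult replicate 1 or 2 the genes called went from 2063 to 1176 or 1157, and without deep replicate 3 to 1502. With only the adult libraries fitted 433 were called, and 15 of the 34 genes named by rule lost their call there or in another setting; none of these is among the genes given above.

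Adult and planula differences overlapped in part. Of the 2063 genes called in adults 66.5% moved the same way in planulae (fry adjusted p = 1.42e-06), and of the 5901 called in planulae 59.3% moved the same way in adults (adjusted p = 0.0667). The share in adults was 63.7% without deep adult replicate 3 (adjusted p = 0.0253). Called in both were 209 genes higher and 293 lower at depth, where unrelated lists would share 119.5 and 115.6. Over all genes called in natives, fry found no balance towards the native direction in translocated juveniles. The shares with the same sign were 60.8% and 52.7% of planula genes at 8 and 60 days (adjusted p = 0.319 and 0.686) and 52.5% and 51.6% of adult genes (adjusted p = 0.604 and 0.281). Genes called both in natives and at 60 days did overlap. Lower in deep adults and in translocated juveniles were 68 genes (14.4 for unrelated lists) and higher in both 21 (10.4), while 24 and 10 went opposite ways (12 and 12.5). For planulae these were 85 (35.1) and 43 (34.9), against 59 (29.3) and 30 (41.9). The convertase gene12209 kept its shallow level in translocated juveniles, at 19.5 CPM at 8 days and 22.4 at 60 days.

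At 8 days the question was what the move to 45 m had changed. Class E basic helix-loop-helix protein 40 (gene8345), a repressor tied to the circadian clock, was the 1 gene called, at 32 ± 4.06 CPM in translocated and 12.7 ± 1.3 in control juveniles (1.33, SE 0.17, adjusted p = 0.00326). The call was lost without control replicate 1 (adjusted p = 0.0863) or 3 (0.0601) and with only the 6 libraries fitted (0.0698). At an unadjusted p under 0.05 there were 1400 genes, where 1287 would be under it with none changed, and DESeq2 called 95. Simulated counts with no gene changed at 8 days also gave 1 call. At 8 days 11 lists passed camera. Fluorescent proteins lay lower (median −1.81, none of 6 called, 3 lower over the list alone, camera adjusted p = 0.000617, adjusted p = 0.181 with an estimated correlation), with a GFP-like protein (gene28123) at 27.1 ± 14.4 against 362 ± 104 CPM (adjusted p = 0.779). Oxidative phosphorylation (median −0.36, camera adjusted p = 2.18e-10, adjusted p = 0.456 with an estimated correlation) and fatty acid oxidation (−0.29, camera adjusted p = 6.11e-08, adjusted p = 0.181 with an estimated correlation) also lay lower, with 0 genes called in each; over the lists alone 6 fell and 2 rose, and 3 fell. Cell cycle and DNA replication lay lower (−0.25, camera adjusted p = 6.2e-07, adjusted p = 0.265 with an estimated correlation).

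Skeletal organic matrix lay higher in translocated 8-day juveniles (median 0.33, none of 181 called, camera adjusted p = 0.000186, adjusted p = 0.181 with an estimated correlation), as did neurons and synapses (0.24, none of 437 called, camera adjusted p = 0.000129, adjusted p = 0.298 with an estimated correlation). Shifts that hung on single libraries were seen in digestive and gland enzymes, extracellular matrix, the proteasome, the ribosome and heat shock proteins (medians 0.28, 0.20, −0.18, −0.16 and 0.10). Camera adjusted p = 0.000617, 0.00128, 0.00379, 0.0127 and 0.0147, and adjusted p = 0.385, 0.456, 0.727, 0.846 and 0.456 with an estimated correlation. Without control replicate 3 the first 4 went to 0.0766, 0.053, 0.0663 and 0.053. The proteasome was also lost without control 1 (0.0653), the ribosome without control 1 (0.711) or translocated 2 (0.0722) or 3 (0.112), and heat shock proteins without control 2 (0.181) or translocated 3 (0.0598). Venom and toxins had no called gene of 12 (median 0.63, adjusted p = 0.0905).

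At 60 days the translocated juveniles had less RNA for respiration and fuel use than the controls of that age. NDUFA4 (gene17976) fell from 144 ± 36.3 to 19.1 ± 3.96 CPM (−2.92, SE 0.31, adjusted p = 4.21e-05), and succinate dehydrogenase assembly factor 2 (gene7709) from 53.9 ± 17 to 12.5 ± 0.606 CPM (−2.11, SE 0.28, adjusted p = 0.000432). Medium-chain acyl-CoA dehydrogenase (gene19811), an early step of fatty acid breakdown, fell from 1580 ± 227 to 410 ± 59.1 CPM (−1.95, SE 0.24, adjusted p = 0.000217), and acyl-CoA dehydrogenase 9 (gene6826) by 1.64 (SE 0.24, adjusted p = 0.000844). Group XV phospholipase A2 (gene16566) fell from 304 ± 43.6 to 74.3 ± 13.3 CPM. Of 56 oxidative phosphorylation genes 11 fell and none rose (18 and 0 over the list alone; median −0.52, camera adjusted p = 2.32e-17, adjusted p = 0.42 with an estimated correlation). Fatty acid oxidation lost 9 of 55 genes and gained none (18 and 2 over the list alone; −0.37, camera adjusted p = 2.92e-08, adjusted p = 0.261 with an estimated correlation). Glycolysis and gluconeogenesis lost 4 of 22 (5 lower and 1 higher over the list alone; −0.35, camera adjusted p = 3.85e-05, adjusted p = 0.368 with an estimated correlation).

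Other energy and transport genes fell at 60 days in the fit of all libraries but were not called when only the 6 libraries were fitted. Phosphoenolpyruvate carboxykinase (gene18452), the entry step of sugar synthesis, went from 808 ± 102 to 162 ± 71.6 CPM (−2.32, SE 0.36, adjusted p = 0.00114 and 0.0714 in the smaller fit). Enolase (gene13500) went from 632 ± 55.6 to 242 ± 47.2 CPM (−1.38, SE 0.17, 0.000173 and 0.0639), apolipoprotein D (gene8824) from 343 ± 53.5 to 42 ± 23.7 CPM (−3.03, SE 0.36, 0.000106 and 0.0639) and the succinate dehydrogenase flavoprotein (gene22267) from 1160 ± 116 to 460 ± 80.5 CPM (−1.34, SE 0.19, 0.000613 and 0.0644). Glutamate dehydrogenase (gene3742) fell by 1.49 (SE 0.21, 0.000557 and 0.073). Upwards, thyrotroph embryonic factor (gene10071), a clock-linked transcription factor, went from 195 ± 32.2 to 655 ± 290 CPM (1.75, SE 0.27, 0.00116 and 0.111). The smaller fit called 31 genes. Of the 43 genes named by rule and called at 60 days, 36 lost their call there or in another setting. With single libraries left out 20 of the 43 lost it. Hemagglutinin/amebocyte aggregation factor (gene23284) rose from 0.0817 ± 0.0387 to 20.8 ± 14.4 CPM (7.84, SE 1.16, adjusted p = 0.000859) and kept its call in every setting.

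At 60 days the cytosolic ribosome, the proteasome and the extracellular matrix list kept their calls with any library left out. The cytosolic ribosome lay higher (median 0.57, none of 82 called, none over the list alone, camera adjusted p = 9.82e-12, adjusted p = 0.475 with an estimated correlation). The proteasome lay lower (−0.46, none of 44 called, none over the list alone, camera adjusted p = 2.92e-08, adjusted p = 0.437 with an estimated correlation). Extracellular matrix and adhesion rose in 4 of 299 genes (1 over the list alone; 0.42, camera adjusted p = 0.000238, adjusted p = 0.437 with an estimated correlation). Neurons, digestive enzymes, innate immunity, antioxidant defence, skeletal matrix and opsins passed with camera adjusted p = 0.00279, 0.00886, 0.0214, 0.0272, 0.0272 and 0.0322 (adjusted p = 0.42, 0.437, 0.42, 0.475, 0.42 and 0.42 with an estimated correlation). Without translocated replicate 2 these 6 went to 0.128, 0.0564, 0.0564, 0.0923, 0.119 and 0.0923. Some were also lost without translocated 1 (antioxidant 0.124, innate 0.0862), translocated 3 (opsins 0.072, skeletal 0.0743, digestive 0.167), control 2 (opsins 0.0522) or control 3 (skeletal 0.197, antioxidant 0.206). With median-ratio scaling the skeletal call was lost as well (camera adjusted p = 0.0606). Of the 616 genes 280 were higher (45.5%), a share that was 57.2% with median-ratio scaling and 61.6% with DESeq2. Without control replicate 2 or 3 the genes called went to 410 or 220, and without translocated replicate 2 or 3 to 349 or 410.

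**Figure D3:**
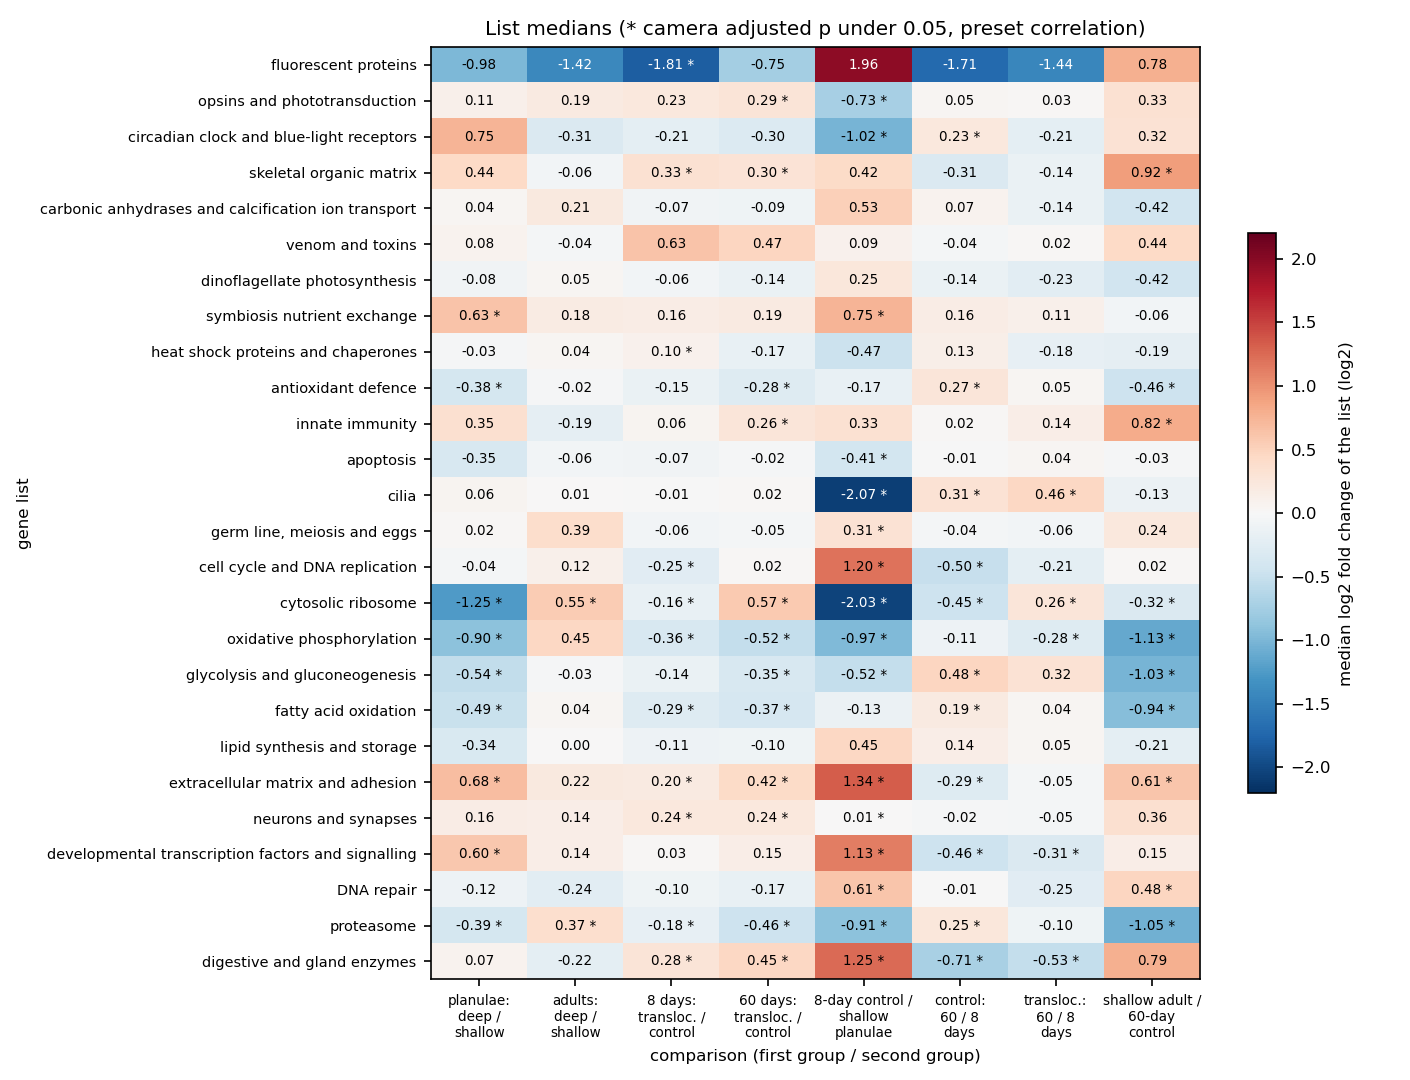
Median log2 fold change of 26 gene lists in 8 comparisons of 2 groups, with stars where camera's adjusted p was under 0.05. The oxidative phosphorylation medians were −0.90 in deep planulae, −0.36 in 8-day and −0.52 in 60-day translocated juveniles, and 0.45 in deep adults.

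**Figure D4:**
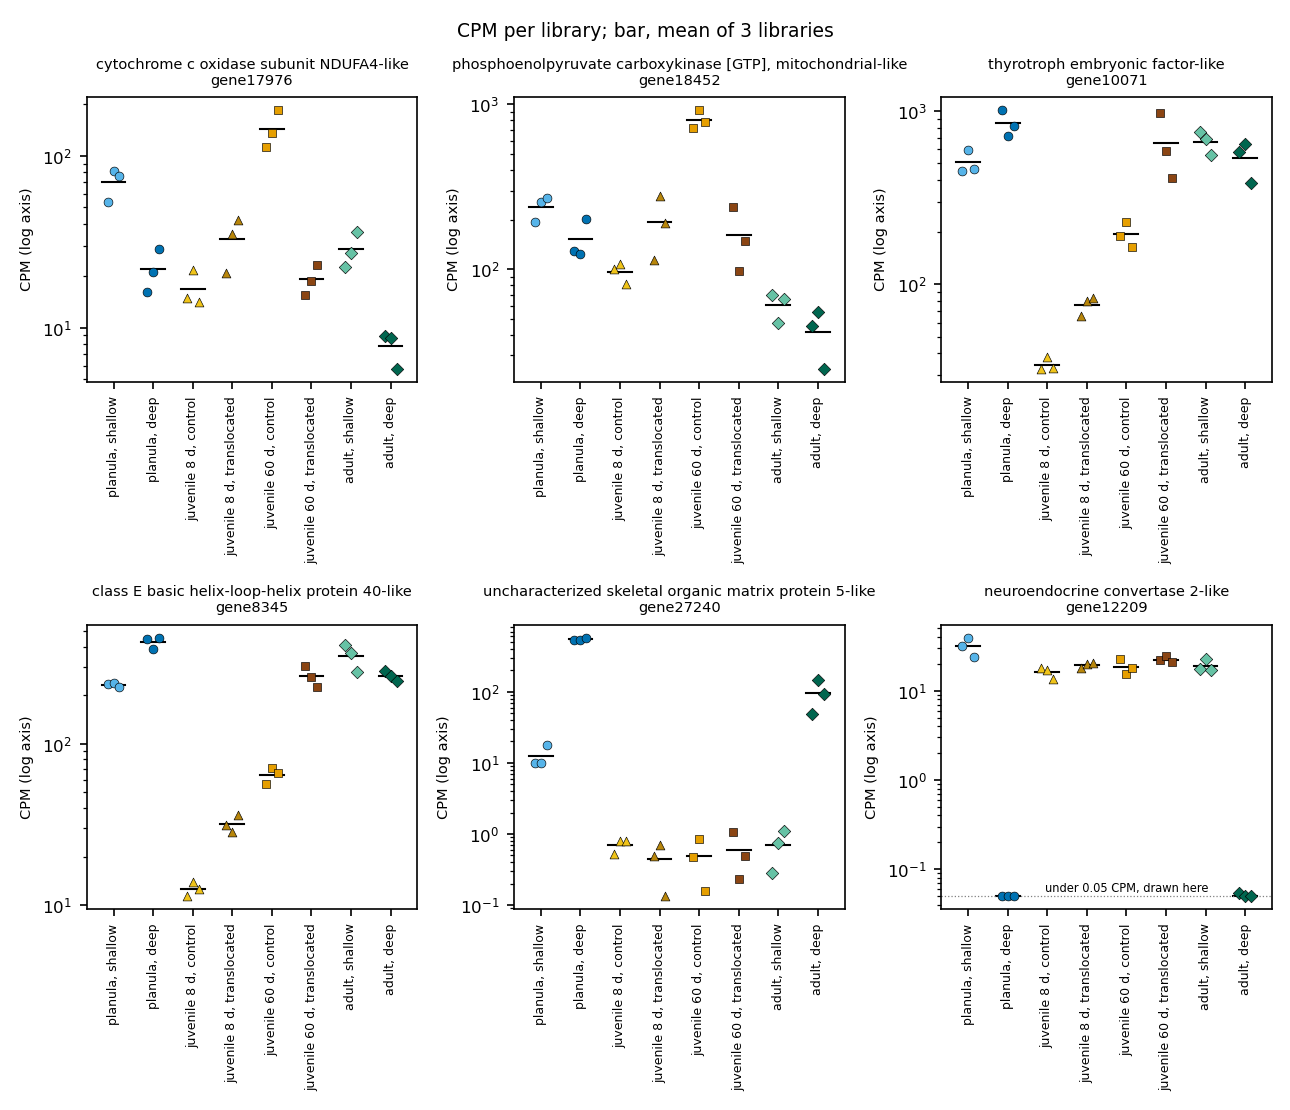
CPM (log axis) of 6 genes in each library, by group; values under 0.05 are drawn at 0.05. Neuroendocrine convertase 2 (gene12209) averaged 31.8 in shallow planulae, with 1 count in all deep ones, and NDUFA4 (gene17976) went from 144 to 19.1 with translocation at 60 days.

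The shallow line was read next for what changes as a planula becomes a polyp. Settlement came with a fall of cilia and ribosome genes and a rise of division genes. Of 124 cilia genes 104 fell and 3 rose (106 and 4 over the list alone; median −2.07, camera adjusted p = 1.43e-47, adjusted p = 0.00431 with an estimated correlation), with dynein regulatory complex subunit 3 (gene20585), part of the beating machinery, going from 279 ± 54.6 to 28.7 ± 1.03 CPM (−3.28, SE 0.21, adjusted p = 1.41e-09). Of 82 ribosome genes 78 fell and none rose (median −2.03, camera adjusted p = 2.96e-31, adjusted p = 0.27 with an estimated correlation), and of 119 cell cycle genes 70 rose and 15 fell (72 and 16 over the list alone; median 1.20, camera adjusted p = 1.36e-07, adjusted p = 0.247 with an estimated correlation). The replication helicase subunit mcm4 (gene18252) went from 3.7 ± 0.383 to 56.1 ± 4.18 CPM. A galaxin (gene13931), a protein of the coral skeleton, had 402 ± 131 CPM in 8-day controls (ratio 16400, 2940 to 648000, adjusted p = 3.16e-07), and carbonic anhydrase 2 (gene19428) was at least 526-fold higher. As lists, skeletal organic matrix (53 rose and 44 fell of 181 genes, camera adjusted p = 0.777) and carbonic anhydrases and ion transport (22 rose and 8 fell of 56, camera adjusted p = 0.0956) did not differ from other genes.

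Opsins and phototransduction fell in 17 and rose in 6 of 43 genes (18 and 6 over the list alone; median −0.73, camera adjusted p = 0.000478, adjusted p = 0.077 with an estimated correlation), with melanopsin-B (gene28817) going from 15 ± 4.5 to 0.101 ± 0.0528 CPM (−7.15, SE 0.61). In the circadian list 6 of 11 fell and 3 rose (7 and 4 over the list alone; −1.02, camera adjusted p = 0.0106, adjusted p = 0.247 with an estimated correlation); thyrotroph embryonic factor (gene10071) went from 504 ± 81 to 34.5 ± 3.11 CPM. Extracellular matrix rose in 126 and fell in 32 of 299 genes (1.34), developmental factors rose in 149 and fell in 56 of 356 (1.13), and digestive enzymes rose in 57 and fell in 18 of 137 (1.25). DNA repair rose in 31 and fell in 6 of 83 (0.61). Over the lists alone these were 129 and 36, 159 and 57, 61 and 18, and 31 and 6. Camera adjusted p = 4.87e-05, 0.000177, 0.00875 and 0.0079, and adjusted p = 0.36, 0.349, 0.399 and 0.378 with an estimated correlation. Oxidative phosphorylation fell in 40 of 56 genes (43 over the list alone; −0.97, camera adjusted p = 3.73e-08, adjusted p = 0.455 with an estimated correlation).

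Some lists were mixed in this step. Germ line, meiosis and eggs rose in 14 and fell in 20 of 73 genes, and neurons and synapses rose in 85 and fell in 126 of 437 (15 and 20, and 97 and 130, over the lists alone; camera adjusted p = 0.0484 for each, adjusted p = 0.247 and 0.498 with an estimated correlation). The germ line median was 0.31, and 0.23 with median-ratio scaling, although more of its genes fell than rose. The neuron median was 0.01, and −0.04 with median-ratio scaling. The germ line call was lost without 8-day control 1 (0.0618), control 3 (0.0724) or shallow planula 1 (0.0536), and the neuron call without control 3 (0.123) or shallow planula 3 (0.0557). Both were lost with median-ratio scaling (camera adjusted p = 0.0537 for each). The germ line call was also lost with a replicate block (0.0529) and the neuron call with the stricter filter (0.0892). An acetylcholine receptor (gene20718) fell from 141 ± 16.1 to 1.98 ± 0.42 CPM (−6.15, SE 0.33, adjusted p = 5.3e-10).

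Between 8 and 60 days control juveniles gained genes of fuel use and cilia and lost genes of division and patterning. NDUFA4 (gene17976) rose from 16.8 ± 4.19 to 144 ± 36.3 CPM (3.09, SE 0.31, adjusted p = 9.18e-06), phosphoenolpyruvate carboxykinase (gene18452) from 96.8 ± 13.4 to 808 ± 102 CPM (3.06, SE 0.37) and catalase (gene3500), which breaks down hydrogen peroxide, from 3470 ± 1010 to 12900 ± 961 CPM (1.90, SE 0.32). Cilia rose in 21 and fell in 1 of 124 genes (25 and 1 over the list alone; median 0.31, camera adjusted p = 5.29e-06, adjusted p = 0.594 with an estimated correlation). Glycolysis rose in 5 of 22 (8 over the list alone; 0.48, camera adjusted p = 7.77e-05, adjusted p = 0.594 with an estimated correlation). Cell cycle fell in 19 and rose in 1 of 119 (30 and 3 over the list alone; −0.50, camera adjusted p = 2.09e-05, adjusted p = 0.594 with an estimated correlation). Developmental factors fell in 43 and rose in 14 of 356 (57 and 17 over the list alone; −0.46, camera adjusted p = 0.000872, adjusted p = 0.594 with an estimated correlation), with notch 1 (gene22598), a receptor of cell fate signalling, going from 92.8 ± 8.03 to 6.45 ± 3.9 CPM. Digestive enzymes fell in 13 and rose in 6 of 137 (22 and 9 over the list alone; −0.71, camera adjusted p = 0.00125, adjusted p = 0.594 with an estimated correlation), and the ribosome lay lower (−0.45, none of 82 called, camera adjusted p = 0.000133, adjusted p = 0.889 with an estimated correlation). Collagen alpha-1(I) (gene23683) fell by 4.22 (SE 0.41, adjusted p = 8.34e-06). Genes called went from 2202 to 1246 without 60-day control 3 and to 1255 or 1330 without 8-day control 1 or 2.

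In translocated juveniles over the same time, cilia and digestive enzymes moved as in controls and the ribosome did not. Thyrotroph embryonic factor (gene10071) rose from 76.4 ± 9.1 to 655 ± 290 CPM (3.10, SE 0.28, adjusted p = 3.3e-06), cilia rose in 19 and fell in 1 of 124 genes (37 and 1 over the list alone; median 0.46, camera adjusted p = 4.36e-10, adjusted p = 0.797 with an estimated correlation), and notch 1 (gene22598) fell by 2.55 (SE 0.37). Digestive enzymes fell in 14 and rose in 2 of 137 genes (27 and 4 over the list alone; −0.53, camera adjusted p = 0.00705, adjusted p = 0.797 with an estimated correlation), a call lost without translocated 60-day replicate 1 (0.0682). The ribosome lay higher (0.26, 1 of 82 fell, camera adjusted p = 0.00992, adjusted p = 0.797 with an estimated correlation), a call lost without translocated 60-day replicate 3 (0.0555). Oxidative phosphorylation (−0.28) and developmental factors (−0.31) also passed camera and lay lower. The oxidative phosphorylation call was lost without 60-day replicate 1 (camera adjusted p = 0.0589) or 2 (0.183), or 8-day replicate 1 (0.158) or 2 (0.0698). The developmental call was lost without 60-day replicate 1 (0.181) or 3 (0.101), or 8-day replicate 1 (0.146). Glutamate dehydrogenase (gene3742) fell from 189 ± 40.8 to 51.4 ± 10.3 CPM (−1.88, SE 0.21, adjusted p = 4.16e-05). Genes called went from 1900 to 1043 without 60-day replicate 1 and to 964 or 893 without 8-day replicate 2 or 3.

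From the 60-day control to the shallow adult, energy genes fell and innate immunity genes rose. The proteasome and antioxidant defence medians were also lower (−1.05 and −0.46). Oxidative phosphorylation fell in 46 of 56 genes (48 over the list alone; median −1.13, camera adjusted p = 2.14e-17, adjusted p = 0.376 with an estimated correlation), fatty acid oxidation in 33 of 55 (34 lower and 1 higher over the list alone; −0.94, camera adjusted p = 7.69e-12, adjusted p = 0.0321 with an estimated correlation) and glycolysis in 13 of 22, with 1 higher (15 and 1 over the list alone; −1.03, camera adjusted p = 3.52e-11, adjusted p = 0.0321 with an estimated correlation). Phosphoenolpyruvate carboxykinase (gene18452) fell from 808 ± 102 to 61 ± 12.2 CPM and catalase (gene3500) from 12900 ± 961 to 1330 ± 190 CPM (−3.28, SE 0.34). Innate immunity rose in 83 and fell in 18 of 267 genes (92 and 18 over the list alone; 0.82, camera adjusted p = 1.64e-05, adjusted p = 0.112 with an estimated correlation), with the DNA-sensing adaptor STING (gene3969) up by 3.80 (SE 0.44, adjusted p = 6.94e-06) and interferon regulatory factor 2 (gene20630) from 1.97 to 32.4 CPM. Skeletal organic matrix rose in 51 and fell in 15 of 181 genes (53 and 17 over the list alone; 0.92, camera adjusted p = 0.0111, adjusted p = 0.376 with an estimated correlation), among them ectin (gene20735), at 69.6 ± 48.4 CPM in adults (ratio 5610, 1010 to 222000). A ZP domain protein (gene22305) fell from 3640 ± 1820 to 20 ± 3.24 CPM (−7.50, SE 0.59, adjusted p = 1.05e-07). Without 60-day control 3 the genes called went from 8060 to 5289.

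The last question was whether the depth effect itself changed with age. The translocation effect differed between 60 and 8 days in 16 genes, 8 each way (1775 at an unadjusted p under 0.05 where chance gives 1287, 188 with DESeq2). NDUFA4 (gene17976) went from 16.8 to 32.7 CPM with translocation at 8 days and from 144 to 19.1 at 60 days (difference −3.87, SE 0.43, adjusted p = 0.000511), and it alone of the named genes kept its call in every setting. The ribosome list moved up relative to 8 days (0.71, none of 82 called, camera adjusted p = 4.48e-17, adjusted p = 0.89 with an estimated correlation). The count ran from 1 to 21 as single libraries were left out, with 4 without 60-day control 3, 2, 6 and 2 without 8-day controls 1, 2 and 3, and 1 and 3 without 8-day translocated replicates 2 and 3.

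The native depth effect differed between adults and planulae in 3365 genes, 1650 more positive in adults and 1715 more negative. Ribosome genes moved most (69 of 82 more positive, 1 more negative, 77 and 1 over the list alone; median 1.76, camera adjusted p = 8.9e-37, adjusted p = 0.506 with an estimated correlation), then oxidative phosphorylation (35 of 56, 44 over the list alone; 1.39, camera adjusted p = 8.44e-17, adjusted p = 0.506 with an estimated correlation). Spondin-1 (gene26965), nearly absent from deep planulae, had 2.28 CPM in deep and 6.23 in shallow adults (adjusted p = 0.00314 for the difference of effects). Without adult shallow replicate 1 or 2 the genes called went to 2211 or 2081, without shallow planula 2 or 3 to 2104 or 1993, and with only the libraries compared to 1193.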

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

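The depth effect differed with age in tests of the difference itself. The effect of translocation was unlike at 60 and 8 days in 16 genes and 6 gene lists, and the native depth effect was unlike in adults and planulae in 3365 genes and 9 lists. With an estimated correlation 0 of these 6 and 0 of these 9 lists passed, and fry passed 0 lists for the translocation effect. Regrouping the libraries tests whether such counts arise without the real groups. For comparisons of 2 groups only 10 splits exist, too few for a share under 0.05. The real split called 5901 genes in planulae against at most 35 in another split, 2063 against 137 in adults, 1 against 0 at 8 days and 616 against 89 at 60 days. For the steps of age it called 10044 against 0, 2202 against 1, 8060 against 7 and 1900 against 3, so 1 split of 10 reached the real count in each. For each difference of effects 2 of 40 regroupings reached the real count, the real one included, so chance cannot be excluded by that count. The other one called 18 genes against 16, and 3522 against 3365; 2 and 7 of the 40 keep 1 of the real pairs of groups whole, and the highest count among those that keep none was 7 and 12. The scheme for these regroupings was changed after its first counts were seen, with 2 of 40 before and after the change.

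For the patterns below, the tests were chosen after the results were seen, apart from the test of a lag in development, whose prediction was written first. The test of abundant genes replaced one relative to all genes, which no scale can move. In deep planulae, ribosomal and respiratory chain genes were lower than in shallow planulae. The 50 most abundant genes held 34% of the counts of shallow and 22.7% of deep planulae, but did not make the whole difference. Scaled to the counts outside them, the ribosome median was −1.05 (−1.33 to −0.86 over the 3 deep libraries), and −0.82 scaled to all counts. The oxidative phosphorylation median was −0.68 (−0.77 to −0.63) and −0.45 on these scales, against −0.90 with TMM. The size of both differences thus depends on the scale. Cilia (−2.07) and ribosomes (−2.03) fell alike at settlement, but the cilia median at depth was 0.06 (quartiles −0.30 and 0.33). That speaks against deep planulae in which cilia and ribosome RNA had fallen together as at settlement. It cannot exclude deep planulae further along that had kept their cilia RNA, since no library lies between the planula and the settled juvenile. Other lists did move the same way at depth and at settlement (oxidative phosphorylation −0.90 and −0.97, extracellular matrix 0.68 and 1.34, developmental factors 0.60 and 1.13, proteasome −0.39 and −0.91), and 1740 genes were higher in both where unrelated lists would share 672.2. Both differences use the same shallow libraries. Their covariance was 0.971 against 0.178 simulated with no effect (at most 0.184), more than noise in those libraries gave. Their correlation was 0.422 against 0.532, which cannot decide, since a change in 1 difference alone lowers it. Whether part of that change is shared stays open, since a state of the shallow planulae alone would enter both differences. Habitat depth and the origin of the parents, the explanations the design gives, were left untested and stay open.

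Genes that differed with depth in adults moved the same way in planulae in 66.5% of cases. If a gene's reads were lost outright in the deep population through sequence variants, genes expressed in both adult groups would lose this, but 66.6% of 1208 such genes kept the sign, against 66.3% of the 855 others. If growth depth acted alike at every stage, the 502 genes called in both would move in juveniles at 45 m too. Their median signed change in 60-day translocated juveniles was 0.02 (−0.04 to 0.10 over the 3 libraries), with sizes of 2.23 in adults and 2.15 in planulae, though 28 were called the same way there and 15 the opposite way. The shares speak against outright loss as the source of the pattern in the 1208 genes only. They cannot exclude outright loss in single genes among the 855 others, such as neuroendocrine convertase 2 (gene12209), with 1 count in all deep adults. Partial loss of reads through variants, population differences and a response acquired over longer than 60 days could each remain, and none was tested.

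Energy metabolism genes were lower in translocated than in control juveniles at 60 days. A lag in development that grew after 8 days would shrink the change with age in genes that change over both depths. For 4836 such genes the ratio of translocated to control medians was 0.963 (1.23 against 1.27). From log2 CPM means it was 0.993, and 0.936 to 1.053 with single libraries left out, a range added after the ratio was seen. The 31 energy metabolism genes among the 4836 changed with age by a median of 0.83 in controls and 0.55 in translocated juveniles. The ratio over all 4836 genes therefore speaks against a general lag and cannot exclude one limited to energy genes. A few abundant genes did not make the difference either, since the oxidative phosphorylation median scaled to the counts outside the 50 most abundant was −0.56 (−0.58 to −0.46 over the 3 translocated libraries), and −0.66 scaled to all counts. With age the oxidative phosphorylation median was −0.11 in controls and −0.28 in translocated juveniles. As a whole, that list thus had no rise in controls to be delayed. Its member NDUFA4 (gene17976) did rise in controls, from 16.8 to 144 CPM, but not in translocated juveniles (32.7 to 19.1 CPM). Glycolysis (0.48 and 0.32) and fatty acid oxidation (0.19 and 0.04) rose in controls as lists. A delay limited to these or to single genes such as NDUFA4 could remain. So could an effect of life at 45 m itself, which the design gives and no test here addressed. A high state of the 60-day controls could give the same difference and was not tested either. NDUFA4 and phosphoenolpyruvate carboxykinase (gene18452) were highest there among the 8 groups (144 and 808 CPM), with shallow planulae next (70.7 and 240 CPM). Oxidative phosphorylation, glycolysis and fatty acid oxidation were also lower in shallow adults than in these controls (medians −1.13, −1.03 and −0.94).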

How the results depend on the processing

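All 8 counts of genes changed between 2 groups and both difference counts stayed within 1.5 times with median-ratio scaling. The other filters moved only the count for the translocation effect over age, from 16 genes to 10 with no filter and 27 with the stricter one. DESeq2 called 3520 genes in adults, 95 and 1679 in 8-day and 60-day translocated juveniles, 3563 and 3324 for control and translocated juveniles over age, and 188 for the translocation effect over age. With only the libraries compared, which leaves fewer residual degrees of freedom, 433 genes were called in adults, 2 at 8 days, 31 at 60 days, 9 for the translocation effect over age and 1193 for the native effect over age. The median SD of log2 CPM between replicates was 0.55 in deep and 0.32 in shallow adults. It was 0.459 and 0.391 in translocated and control 60-day juveniles, and 0.317 and 0.30 at 8 days. The fit of all libraries pools these spreads, so its p-values may be too small for the groups with the widest spread. With a correlation estimated from the residuals no list passed (0 in place of 9 in planulae, 2 in adults, 11 and 12 in 8-day and 60-day juveniles, 11 and 5 in controls and translocated juveniles over age, 6 and 9 for the differences), except 1 at settlement and 2 from 60 days to adult. Fry passed 0 lists in adults, 0 and 4 in 8-day and 60-day juveniles, 6 and 1 over age in controls and translocated juveniles, and 0 for the translocation effect over age. Over all comparisons, 4 list calls were lost with median-ratio scaling, 6 with the stricter filter and 3 with a replicate block. Among planula genes with an absolute log2 fold change over 1, 63.8% moved the same way in adults (adjusted p = 0.00629). The first component held 49.8% of variance with the 500 most variable genes. The cause was not tested in these cases.

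With single libraries left out, genes called ran from 3757 to 5790 in planulae, 1157 to 2962 in adults, 0 to 8 and 220 to 577 in 8-day and 60-day juveniles, 1246 to 1879 and 893 to 1473 over age in controls and translocated juveniles, 5289 to 7147 from 60 days to adult, and 1 to 21 and 1993 to 4317 for the differences. Lists past the threshold ran from 0 to 3 in adults, 7 to 11 and 6 to 13 in juveniles, 6 to 12 and 3 to 6 over age, and 2 to 7 for the translocation effect over age. The share of planula genes moving the same way in adults ran from 54.6% to 63.7%. The proteasome median in adults ran from −0.03 without deep adult replicate 3, which reverses it, to 0.56. The lower totals of deep adults (16.17 M) and translocated 60-day juveniles (16.91 M) limit what could be called for weakly expressed genes there.

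Samples of different groups share replicate numbers and, apart from adults, letters in the column names, which the labels do not explain. Same-numbered samples did not deviate together (correlations −0.16 to 0.26, and in no comparison were all 3 over 0.1). A check of the letters, added after the other results were seen, gave −0.20 to 0.26, with both shared letters over 0.1 only at settlement (0.15 and 0.16), and no fit used them. With a replicate block the genes called were 5473 in planulae, 1891 in adults, 1 and 591 in 8-day and 60-day juveniles, 9609, 2016, 7527 and 1680 over the steps of age, and 12 and 3332 for the differences, and lists past the threshold over age in translocated juveniles went from 5 to 3.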

Other observations

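The genes in this paragraph were picked after their values were seen. Single genes tied to the clock and to light differed with depth in young corals, in both directions, while the circadian list did not (camera adjusted p = 0.2 in planulae, 0.192 at 8 days and 0.971 at 60 days). The helix-loop-helix repressor gene8345 was higher in deep planulae (428 ± 36.7 against 232 ± 5.75 CPM, log2 fold change 0.88, adjusted p = 0.000932) and in translocated juveniles at 60 days (262 ± 39.3 against 64.3 ± 7.32 CPM, 2.03, adjusted p = 4.65e-06), but not in adults (−0.42, adjusted p = 0.122). Thyrotroph embryonic factor (gene10071) was higher in deep planulae (848 ± 147 against 504 ± 81 CPM, adjusted p = 0.0456) and in 60-day translocated juveniles, and was not called at 8 days (adjusted p = 0.317). Photolyase (gene15271), which repairs ultraviolet damage to DNA with light energy, fell from 91.4 ± 15.3 to 28.2 ± 4.24 CPM with translocation at 60 days (−1.70, adjusted p = 4.21e-05) and was lower in deep adults (−1.08, adjusted p = 0.000814). Heat shock factor 1 (gene1) rose from 354 ± 192 to 2130 ± 1310 CPM at 60 days (adjusted p = 0.00794). At 8 days it had 3030 ± 1250 CPM in translocated and 996 ± 351 in control juveniles (adjusted p = 0.569). Early growth response protein 1 (gene4767) and AP-1 (gene5923) had SDs above their means in translocated 60-day juveniles (3780 ± 5440 and 1500 ± 2190 CPM). Neither was called there (adjusted p = 0.442 and 0.141). The hour of collection is not given in the sources used here.

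A few very abundant genes also differed. A c-Fos-like transcription factor (gene5217) held 59900 ± 8600 CPM in shallow planulae and 28500 ± 1230 in deep ones (−1.07, adjusted p = 0.00126), and rose from 17500 ± 3330 to 32300 ± 972 CPM with translocation at 60 days (0.89, adjusted p = 0.0252). Less abundant genes of the same name were called in neither comparison. Adjusted p was 0.93 and 0.122 for gene20908, and 0.157 and 0.783 for gene12870. Vitellogenin (gene3329), a yolk protein, rose from 17.9 ± 21.9 CPM in shallow planulae to 2880 ± 1260 in 8-day controls (7.33, adjusted p = 3.02e-06).

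One hypothesis was that the response at 60 days had begun by 8 days below the threshold of the test, and its prediction was written ahead of the test. Of the 616 genes called at 60 days, 480 (77.9%) had the same sign at 8 days, with a median signed change of 0.30 against 1.46 at 60 days. Both parts of the prediction, at least 65% with the same sign and a fry test under 0.05, were met. The test cannot tell a response that grows over time from a steady difference between the sites, which remains possible.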
